A study of Homo sapiens with 14 samples.

How the data were processed

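Gene expression was measured by paired-end RNA sequencing (50 cycles, 18 cycles of library PCR) of polyA RNA from 6 established breast cancer cell lines, 5 days after transfection with siRNA pools. There were 14 libraries: siControl and siJARID1B in MCF7, T-47D, SUM185PE, SUM159PT, MDA-MB-231 and HCC2157, and siCTCF in MCF7 and SUM185PE. No line had a second library of one siRNA. Cell line and siRNA came from the sample labels. The luminal and basal classes came from textbooks and were fixed before the files were opened.

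The authors deposited 1 table per library with a gene symbol, its read counts as whole numbers, and a length, with no coordinates. The submitters' processing notes name CASAVA 1.7, TopHat and genome build hg19. The counting program, its annotation and its use of strand are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. Tables of 10 libraries had 23263 genes and those of MDA-MB-231 and HCC2157 had 23349, so 2 gene lists were used, and they part the cell lines. The 23145 shared symbols were kept. The 118 or 204 symbols outside them held 0.121% to 0.190% of the counts of a library, and 325 shared genes had another length in the second list.

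Depth per library, in mega-counts (M), ran from 7.27 M to 38.6 M: 29.1, 27.3 and 26.1 M in MCF7 (siControl, siJARID1B, siCTCF), 38.6 and 18.4 in T-47D, 9.85, 9.11 and 25.0 in SUM185PE, 7.27 and 12.8 in SUM159PT, 35.4 and 33.4 in MDA-MB-231, and 25.6 and 31.6 in HCC2157. A gene with 0 counts can hold up to 3 counts by chance, which is 0.0711 to 0.423 CPM in these libraries. Ratios with 0 counts on one side are given as bounds from that floor. Intervals of the ratio in a single line are exact binomial 95% intervals of the 2 counts and cover counting error only.

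Counts were scaled by TMM, filtered with filterByExpr and fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A knockdown was paired with the control of the same cell line by a term for the line. The comparisons were siJARID1B over 6 lines (12 libraries), siJARID1B within luminal and within basal lines and the difference of these 2 effects (the same 12 libraries, 1 shared spread), siCTCF (all 14 libraries, 1 shared spread), siCTCF against siJARID1B (the 6 libraries of MCF7 and SUM185PE) and luminal against basal lines with control siRNA (6 libraries). The spread of the siCTCF comparison therefore comes mostly from lines that did not get siCTCF. In that fit the siJARID1B libraries, with 1 effect shared by all lines, also set the level of a line beside its control. Comparisons, tests, gene lists and most alternatives were fixed before the files were opened.

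Genes are named by a rule fixed in advance. In each direction the 10 called genes with the largest log2 fold change are named if their mean CPM is at least 2 and every line moved the same way (for classes, if they do not overlap). Fewer than 5 were filled by the lowest p-value without a call. A log2 difference of 0 counts as no direction. Symbols of loci without a name, of microRNA and of snoRNA genes were counted but not named. In single lines the 3 genes with the largest rise and fall are named from log2 CPM with a prior count of 5 and at least 100 counts in the pair.

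Of 22 gene lists 21 could be tested, since the files hold no mitochondrially encoded gene. The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with the correlation estimated from the data and fry, adjusted over the lists of a comparison. Members were also adjusted over their list alone. Correlations between knockdowns were computed over 12452 genes, beside 100 simulations without effects that shared the control. GC content came from the longest GENCODE transcript of each symbol and covered 90.1% of these genes (11214). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

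The alternatives fixed in advance were RLE size factors, library size only, no filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, each cell line left out, no term for the line, other sets of libraries, and other prior counts and filters for the correlation. Added after the results were seen were a correction for GC content, fits within the lines of 1 gene list, the genes with the same length in both gene lists, and the PCDHB genes alone. For chance groupings, 80 of the 452 splits of the 12 libraries that can be fitted (462 in all) were drawn, with all 32 swaps of labels within pairs and all 10 splits into 3 and 3 of the 6 luminal libraries, of the 6 basal libraries, and of the 6 lines for the difference of the classes and for control siRNA.

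The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The first simulation took each gene's own dispersion and gave false calls of 17.4% (siJARID1B over 6 lines), 18.2% (luminal), 18.1% (basal), 15.3% (difference of the classes), 12.2% (siCTCF), 14.1% (siCTCF against siJARID1B) and 0% (control siRNA). The model was then changed, after that result was seen, to dispersions drawn around the trend. It gave 7.04%, 10.1%, 9.78%, 6.30%, 5%, 0% and 0%, and recovered 86%, 66%, 69%, 27%, 24%, 0% and 0% of the 2-fold and 99%, 95%, 97%, 92%, 90%, 0% and 0% of the 4-fold changes. DESeq2 gave 16.1%, 14.3%, 12.8%, 11.9%, 19.9%, 41.1% and 93.8% false calls there. With no list shifted, none was called. The simulated genes were drawn independently, so this could not show false list calls from genes that move together. A list shifted by 1.5 times was recovered at the preset correlation except with control siRNA (adjusted p = 0.749). With the estimated correlation it was also missed for the difference of the classes and for siCTCF against siJARID1B. For siCTCF against siJARID1B a line was left out of the fit of all 14 libraries, since 3 libraries leave no spread to estimate.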

Results

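The histone demethylase JARID1B, now named KDM5B, and the insulator protein CTCF were each reduced with pools of small interfering RNA (siRNA) in established human breast cancer cell lines. KDM5B removes methyl groups from lysine 4 of histone H3, a mark of active promoters, and CTCF stops the loops that cohesin extrudes along chromatin. RNA was sequenced from 14 libraries of 6 lines: siControl and siJARID1B in all 6, and siCTCF in MCF7 and SUM185PE. MCF7, T-47D and SUM185PE are treated here as luminal, and SUM159PT, MDA-MB-231 and HCC2157 as basal, from textbook classes that the sample labels do not give. The gene tables held from 7269183 (SUM159PT siControl) to 38616767 (T-47D siControl) counts. Each line and siRNA had 1 library and no replicate library, so the p-values below measure the spread between lines, and the intervals of single lines cover counting error only.

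KDM5B, the target of siJARID1B, fell in all 6 lines. It kept 17.5% of its control level in MCF7 (95% interval 16.3 to 18.8), 14.1% in T-47D (13.1 to 15.1), 30.0% in SUM185PE (27.3 to 32.8), 10.7% in SUM159PT (8.75 to 13.1), 14.9% in MDA-MB-231 (13.4 to 16.5) and 30.6% in HCC2157 (28.8 to 32.4). Over the 6 lines the log2 fold change of KDM5B was -2.43 (SE 0.19, adjusted p = 0.00089), from 169.7 ± 71.7 to 34.6 ± 20.4 CPM (counts scaled by library size, mean ± SD, n = 6). CTCF fell to 21% (19.2 to 23.0) in MCF7 and 20.3% (18.1 to 22.8) in SUM185PE after siCTCF, a log2 fold change of -2.30 (SE 0.14, adjusted p = 1.69e-05), from 99.9 ± 21.4 to 20.7 ± 4.92 CPM (n = 2). The other target stood near its control level except in SUM159PT: KDM5B was 109% in MCF7 and 102% in SUM185PE after siCTCF, and CTCF 74.8% (64.0 to 87.4) in SUM159PT and 92.7% to 105% in the other 5 lines after siJARID1B.

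**Figure D1:**
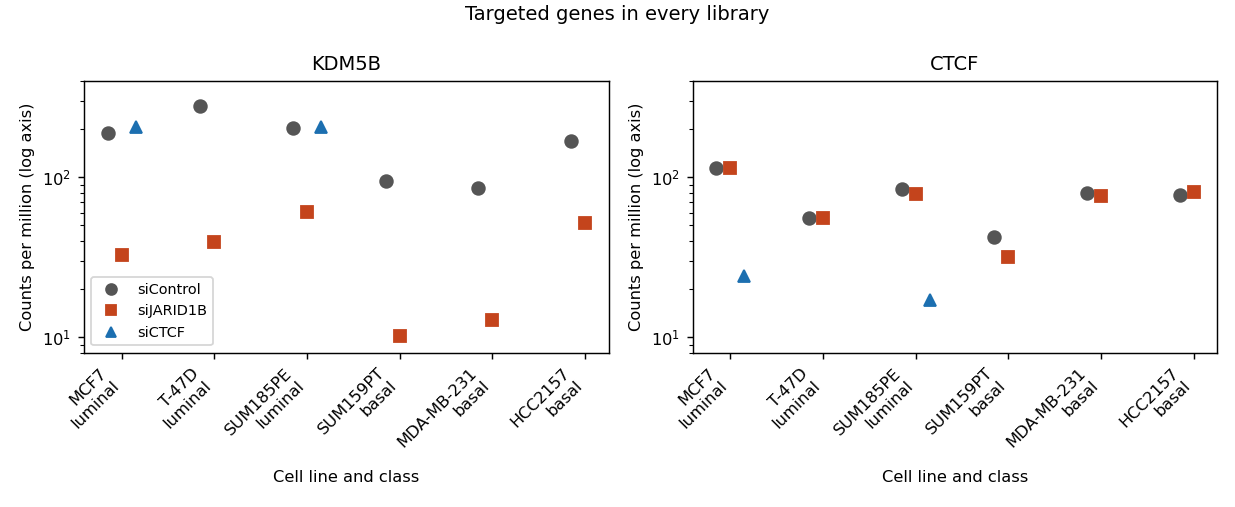
KDM5B and CTCF in each cell line after siControl, siJARID1B and siCTCF, in CPM on a log axis. Each marker is a single library, and no intervals are drawn.

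KDM5B was the only gene called over the 6 lines after siJARID1B. The genes named next did not pass the test. They have the lowest p-values in each direction among genes that moved one way in all 6 lines. That shared direction is a condition of the naming rule and no result. HEY1, a Notch target and transcriptional repressor, had a log2 fold change of 1.04 (SE 0.21, adjusted p = 0.294), SEMA7A, a membrane-anchored semaphorin, 0.59 and GPCPD1, a choline-releasing phosphodiesterase, 0.47. On the other side stood the septin gene SEPT8 (-0.70), FAM115A (-0.99), the imprinted growth regulator PHLDA2 (-0.79) and the spliceosome gene LSM3 (-1.07), each with an adjusted p of 0.194. The small RNA genes SNAR-A10 and SNAR-A11 (both 1.52) are near-identical copies, so their reads cannot be told apart. Of 17410 genes tested, 1087 had an unadjusted p under 0.05 (428 higher, 659 lower). DESeq2 called 40 genes (20 up, 20 down), limma-voom 4, and the fit without SUM159PT 49 (12 up, 37 down).

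Ribosomal protein genes, which share their growth control, were higher after siJARID1B in 32 of 33 members (median log2 fold change 0.14). They passed a competitive list test, camera with a preset correlation between genes (adjusted p = 1.23e-12; 0.607 with the correlation estimated from these libraries). Genes of the unfolded protein and integrated stress responses (median 0.22, 21 of 23 higher, adjusted p = 4.54e-05; 0.607 with the estimate) and of G2/M and mitosis (0.10, 21 of 25 higher, 0.0248; 0.748) also passed upward. Basal and mesenchymal markers passed upward with a median of 0.02 (mean 0.14, 20 of 30 higher, 0.00978; 0.607). Metallothioneins, which bind zinc and copper, were lower in 9 of 9 members in the fit (-0.55, adjusted p = 0.00443; 0.607), though by line the median of 5 members was 0.28 in T-47D, 0.33 in SUM185PE and -1.01 to -0.17 in the other 4 lines. Also lower were interferon-stimulated genes (-0.15, 22 of 27 lower, 0.0138; 0.607) and endothelial and stromal markers (-0.41, 10 of 13 lower, 0.0297; 0.607), of which 4 passed when adjusted over the list alone. No list was called with the estimated correlation or by the rotation test fry (0.562 to 0.792 for these 7), and the adjusted p of the other 14 lists ran from 0.068 (S phase) to 0.868 (luminal markers). Without SUM159PT the stress genes (0.723), metallothioneins (0.161) and endothelial and stromal markers (0.542) lost the call and G2/M turned downward (median -0.06, 0.0428). The calls also ended without MCF7 (basal markers 0.0689), T-47D (interferon 0.372), SUM185PE (basal markers 0.0562, G2/M 0.141), MDA-MB-231 (endothelial and stromal 0.0859) or HCC2157 (interferon 0.0766).

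In single lines the siJARID1B response differed in its genes and in its width. In MCF7 the gap junction gene GJA1 was 4.88-fold its control level, the YAP target CTGF 3.22-fold and the tight junction gene CLDN1 3.14-fold, with LSM3 at 22.8% and the epidermal caspase CASP14 at 40.5%. In T-47D the small RNA genes RMRP (5.91-fold), RPPH1 (5.48-fold) and SCARNA2 (4.89-fold) led, beside a rise of all small non-coding RNA genes from 458 to 1424 CPM in the same library, and the hair keratin KRT36 went from 135 counts to 0 (at least 22.0-fold lower). In SUM185PE the ciliary regulator FOXJ1 (4.23-fold), the axon guidance receptor ROBO2 (4.30-fold) and EYA1 (4.06-fold) were higher, and PLCXD3 (7.59%), CLEC7A (10.5%) and KRT3 (14.4%) lower. SUM159PT gave the heat shock genes HSPA7 (31-fold, interval 15.6 to 72.2) and HSPA6 (26.0-fold), which share sequence, and the stress regulator DDIT3 (22.7-fold). RANBP3L stood there at 3 counts (0.321%, interval 0.0661 to 0.944), the secreted glycoprotein CHI3L1 at 1.64% and the betaine transporter SLC6A12 at 2.85%.

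MDA-MB-231 had higher SCARNA10 (5.69-fold), the cytokine CSF3 (2.80-fold) and RNU4ATAC (2.79-fold) after siJARID1B, with CDK18 at 27.5% and FER1L4 at 30.7%. Its small non-coding RNA genes together went from 372 to 929.7 CPM. HCC2157 had higher REXO1L2P (2.85-fold), the T-box gene TBX2 (2.74-fold) and TOX3 (1.87-fold), with the retinoid-response gene RARRES1 at 46.9% and SCARNA16 at 51.2%. The SD of the log2 fold changes was 0.66 in SUM159PT and 0.15 to 0.30 in the other 5 lines, and 407 genes were at least 2-fold higher and 718 at least 2-fold lower in SUM159PT, against 3 to 65 and 6 to 39 elsewhere. These single-pair values have no replicate to test them.

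**Figure D2:**
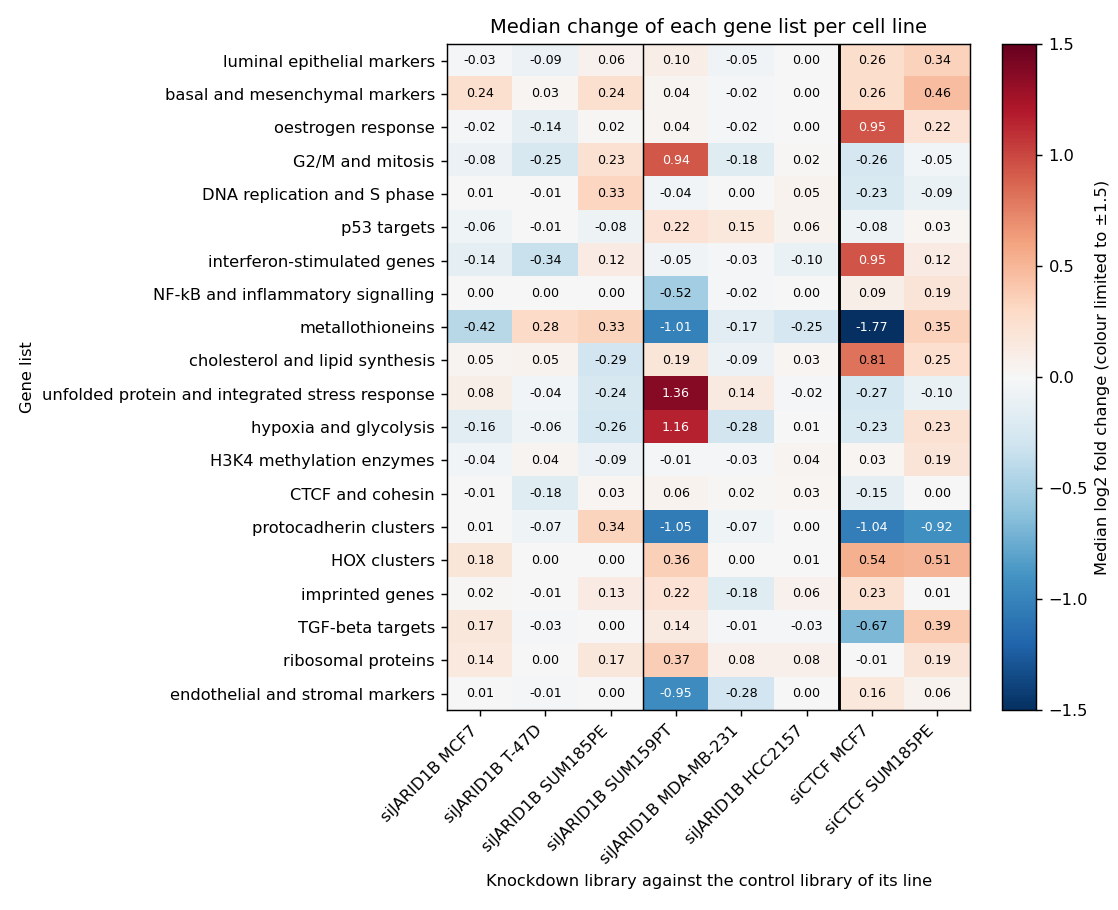
Median log2 fold change of 20 gene lists in each knockdown and cell line against the siControl library of the same line.

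In the fit for the 3 luminal lines, basal and mesenchymal markers were higher after siJARID1B (23 of 30 members). These are markers of another cell class, but the luminal lines do not lack all of them. With control siRNA, ITGB4 stood at 449, 131 and 275 CPM in MCF7, T-47D and SUM185PE, and VIM at 0.11, 0.21 and 0.56. By line the median was 0.24 in MCF7, 0.03 in T-47D and 0.24 in SUM185PE. Of the 30 members 10 were higher in all 3 lines and 0 lower in all 3. If each line went up or down at random, 12.5% would be higher in all 3. Among the 10, CD44 in SUM185PE (0.094 to 0.099 CPM) stood below the floor of 3 counts. So did CAV1 (0.024 to 0.048 CPM) and CAV2 (0 to 0.048 CPM) in T-47D, so those rises are not measured. The list passed (median 0.24 in the fit, adjusted p = 1.37e-05; 0.140 with the estimated correlation, 0.139 in the rotation test fry), and the laminin chain LAMB3 (0.64) and fibronectin, FN1 (0.71), passed when adjusted over the list alone. The annexin ANXA1 (0.94) and the receptor kinase AXL (0.49) did not pass. Ribosomal protein genes (0.10, 32 of 33 higher, adjusted p = 3.32e-07; 0.750), clustered protocadherins (0.03, 51 of 52, 0.000736; 0.750), S phase genes (0.10, 25 of 28, 0.00165; 0.750) and TGF-beta targets (0.09, 14 of 20, 0.00807; 0.750) passed upward, the last with CTGF alone passing within the list. Interferon-stimulated genes passed downward (-0.20, 22 of 27 lower, 0.00807; 0.750). These counts of members are from the fit. By line, protocadherins were higher in 27 of 52 members in MCF7, 9 in T-47D and 40 in SUM185PE. S phase genes were higher there in 15, 13 and 24 of 28 members. Without SUM185PE the protocadherins and S phase genes lost the call (0.588 each), as did the interferon genes without T-47D (0.858) and TGF-beta targets without MCF7 (0.206). The other 5 calls had a fry p of 0.566 to 0.914, and the other 15 lists an adjusted p of 0.136 to 0.907.

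**Figure D3:**
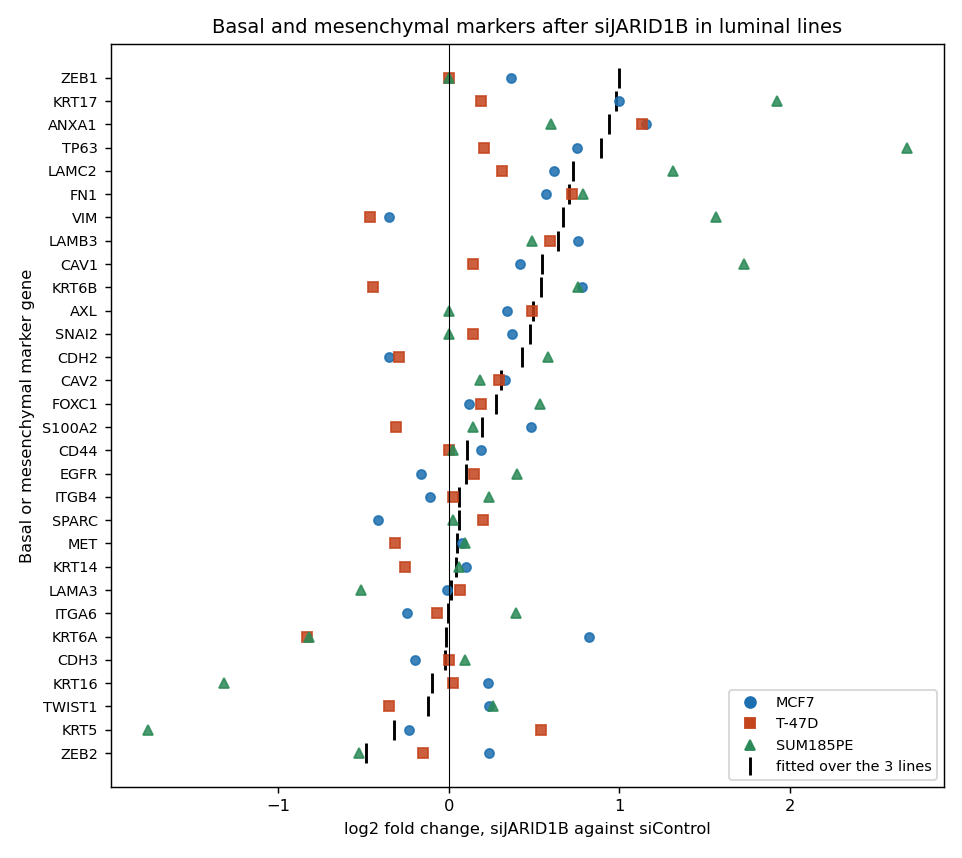
Log2 fold change of basal and mesenchymal marker genes after siJARID1B in each luminal line (MCF7, T-47D and SUM185PE), with a tick for the value fitted over these lines.

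KDM5B itself was the only gene called in the luminal lines (-2.35, SE 0.26, adjusted p = 0.0442; 222.9 ± 48.0 to 44.3 ± 14.6 CPM, n = 3). The matricellular YAP target CTGF came next at 1.86 (SE 0.25, adjusted p = 0.133). Among genes that moved one way in all 3 lines, LAMB3, ANKRD30BL (1.42), FN1 (adjusted p = 0.827) and FOXJ1 (2.09) followed. LSM3 (-1.31), the kinase gene UHMK1 (-0.72), SEPT8 (-0.70) and PHLDA2 (-0.82) were the lowest by p-value among such genes on the other side, all without a call. ANKRD30BL is 1 of 6 symbols treated here as ribosomal RNA loci. Together these went from 40.8 to 64.7 CPM in MCF7, 55.0 to 306 in T-47D and 79.6 to 165 in SUM185PE. ANKRD30BL was also higher after siCTCF (1.81 in MCF7, 1.65 in SUM185PE). FOXJ1 rests on SUM185PE (300 of 312 counts after siJARID1B), and CTGF was at 0.01 in T-47D. Luminal markers did not pass as a list (adjusted p = 0.906) and none of their members was called. Unadjusted, 489 genes had p under 0.05 (281 higher, 208 lower). DESeq2 called 7, limma-voom 1 and a fit of the 6 luminal libraries alone 54 (42 up, 12 down). The call of KDM5B ended without MCF7, T-47D or SUM185PE (0 genes each), with its log2 fold change at -2.66 to -2.12 over the left-out lines, and without SUM159PT 41 genes were called.

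In the 3 basal lines, siJARID1B lowered the acute-phase genes SAA1 (-1.16, SE 0.15), SAA2 (-1.39) and their readthrough SAA2-SAA4 (-1.32), whose near-identical sequences share reads. SAA1 stood at -1.46, -0.90 and -0.80 in SUM159PT, MDA-MB-231 and HCC2157. KDM5B (-2.52) fell too. The deiodinase DIO2 (-2.30) and the glycosyltransferase GALNTL2 (-2.35) were called on SUM159PT (-2.54 and -2.38), since the other 2 basal lines held 15 counts or fewer of either, and DIO2 was at -0.77 without SUM159PT. The adjusted p of these 6 genes was 0.0154 to 0.0359. The other 7 called genes, all downward, did not move the same way in all 3 lines: the sulfatase SULF2 (-2.81), the cyclooxygenase PTGS1 (-1.66), the decoy receptor IL1R2 (-3.37), the paired acute-phase genes ORM1 (-2.83) and ORM2 (-3.04), SLC6A12 (-4.88) and the transporter ABCC3 (-1.17). In all 13 genes were called and 1140 had an unadjusted p under 0.05 (404 higher, 736 lower), with 30 called by DESeq2 and 22 by limma-voom. All calls ended without MCF7, T-47D or SUM185PE (0 genes each), whose pairs add to the shared spread, and in a fit of the 6 basal libraries (0 genes). SAA1 stayed at -1.35 to -0.91 over the left-out lines. The count was 10 without SUM159PT, 23 without MDA-MB-231 and 25 without HCC2157.

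Among lists in the basal lines, ribosomal protein genes (0.17, 32 of 33 higher, adjusted p = 1.62e-09; 0.649 with the estimated correlation) and genes of the unfolded protein and integrated stress responses (0.46, 22 of 23, 1.10e-06; 0.649) passed upward. So did G2/M genes (0.21, 24 of 25, 0.000592; 0.842), hypoxia and glycolysis genes (0.23, 19 of 23, 0.0141; 0.850) and p53 targets (0.16, 15 of 23, 0.0216; 0.649), with SESN2 at 0.82, GDF15 at 0.76 and CDKN1A at 0.60, none of them called. Protocadherins (-0.28, 49 of 52 lower, 1.12e-05; 0.649), metallothioneins (-0.63, 9 of 9, 6.59e-05; 0.649) and endothelial and stromal markers (-0.43, 11 of 13, 0.000525; 0.649) passed downward. Of the stromal list 8 genes passed when adjusted over the list alone, among them the growth factor receptors PDGFRA (-1.79) and PDGFRB (-1.20). Without SUM159PT the stress genes (0.766) and protocadherins (0.238) lost the call, and G2/M (-0.10, 0.0278) and hypoxia genes (-0.15, 4.57e-05) turned downward. Without MDA-MB-231 the p53 targets lost it (0.165). The rotation test fry called none of the 8 (0.412 to 0.758), and the other 13 lists had an adjusted p of 0.157 to 0.911.

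No single gene was called as different between luminal and basal lines in its siJARID1B response. By the naming rule only genes whose classes do not overlap are given here. Among them the lowest p-values, luminal minus basal, were those of DIO2 (2.45, adjusted p = 0.728), FN1 (1.05), the laminin receptor BCAM (0.77), the collagen receptor MRC2 (1.04) and ST6GAL1 (1.04). DIO2 was at 0.86 without SUM159PT and 4.82 without MCF7. The other way stood the GTPase RAB39B (-4.34), CGRRF1 (-0.78), the ERK phosphatase DUSP5 (-1.0), BRP44L (-0.69) and YOD1 (-0.76). Without SUM159PT RAB39B was at -2.34, DUSP5 at -0.58 and YOD1 at -0.50. Unadjusted, 431 genes had p under 0.05 (286 higher, 145 lower), DESeq2 and limma-voom called 0 each, and the count was 2 without a filter, 1 without SUM159PT, 2 without MDA-MB-231 and 1 without HCC2157. Simulated data gave back 27% of 2-fold differences in this comparison.

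Protocadherins responded more upward in luminal than in basal lines (median difference 0.38, adjusted p = 2.50e-09; 0.661 with the estimated correlation), with per-line medians of 0.34 in SUM185PE, -1.05 in SUM159PT and -0.07 to 0.01 in the other 4 lines. So did basal markers (0.21, 0.00125; 0.248), endothelial and stromal markers (0.43, 0.0126; 0.716), TGF-beta targets (0.14, 0.0425; 0.661) and S phase genes (0.14, 0.0449; 0.742). Stress response genes (-0.47, 0.00046; 0.742), G2/M genes (-0.26, 0.00318; 0.742), p53 targets (-0.26, 0.00532; 0.248) and hypoxia genes (-0.35, 0.00901; 0.742) responded more upward in the basal lines. The rotation test fry called none of the 9 (0.174 to 0.728). Without SUM159PT the S phase (0.132) and stress calls (median -0.05, 0.964) ended, and the G2/M (0.04, 0.277) and hypoxia (0.03, 0.0975) calls ended with medians on the other side of 0. G2/M also ended without T-47D (0.117), as did the stromal list (0.0521). S phase ended without SUM185PE (0.760) or HCC2157 (0.125), and TGF-beta targets without MCF7 (0.135), SUM185PE (0.0519), MDA-MB-231 (0.129) or HCC2157 (0.158). The other 12 lists had an adjusted p of 0.0531 to 0.973.

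After siCTCF many genes moved in MCF7 and SUM185PE. Small non-coding RNA genes together went from 248 to 532 CPM in MCF7 and from 458 to 1154 in SUM185PE. The 6 symbols of ribosomal RNA loci went from 40.8 to 235 and from 79.6 to 389 CPM. Whether these rises bear on the calls was not tested. KRT9, a keratin of palm and sole skin, went from 0 counts in both controls to 660 (adjusted p = 4.71e-05), 650 of them in MCF7 (at least 255-fold there), and the calmodulin-binding gene PCP4 rose by a log2 fold change of 5.83 (SE 0.40, adjusted p = 8.91e-05; 46 to 2471 counts). The peptidoglycan amidase PGLYRP2 (5.60), the progesterone receptor gene PGR (4.71, SE 0.32, adjusted p = 4.71e-05), AFF2 (5.01), the immune checkpoint ligand CD274 (3.99) and the protease inhibitor SERPINA1 (3.65) rose too. The kallikrein KLK8 (3 to 117 counts), THRSP (3 to 198) and the glucose transporter SLC2A14 (1 to 51, a paralog of SLC2A3 that may share its reads) started from almost no counts.

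Lower after siCTCF were QDPR, which recycles tetrahydrobiopterin (-3.39, SE 0.26, adjusted p = 5.02e-05), the Wnt antagonist NKD2 (-3.83), EPDR1 (-3.46), TMC7 (-3.22), the zinc finger gene ZBTB39 (-2.87), the carboxypeptidase inhibitor LXN (-2.84), the mitochondrial pyrophosphatase PPA2 (-2.53), DEF8 (-2.49, SE 0.14, adjusted p = 1.69e-05) and MOB3B (20 counts to 3). In all 1071 of 17496 genes were called, 742 up and 329 down, of which 701 and 303 moved the same way in both lines. Unadjusted, 3895 had p under 0.05. DESeq2 called 1911 (1179 up, 732 down) and limma-voom 1439.

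The size of the siCTCF call rests on pairs of other lines. The count was 10 (6 up, 4 down) in a fit of the 6 libraries of MCF7 and SUM185PE and 2 in their 4 siControl and siCTCF libraries. It was 224 without MCF7, 516 without T-47D, 1956 without SUM185PE, 2179 without SUM159PT, 685 without MDA-MB-231 and 645 without HCC2157. Of the 19 genes named above besides CTCF, 6 kept their call without MCF7 (AFF2, QDPR, TMC7, ZBTB39, PPA2 and DEF8) and 18 without SUM185PE (all but MOB3B). The control of SUM185PE held 0 counts of KRT9, PCP4, PGLYRP2, KLK8, THRSP and SLC2A14, 1 of PGR and NKD2 and 2 of LXN, so these changes have no measured size in SUM185PE alone. The MCF7 control held 0 counts of KRT9 and AFF2, 1 of SLC2A14 and 3 of KLK8, THRSP and CD274, so these have none in MCF7 alone. SERPINA1 was at 2.01 without MCF7 and 4.40 without SUM185PE, TMC7 at -2.35 and -4.93, and CD274 at 1.25 without MCF7.

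**Figure D4:**
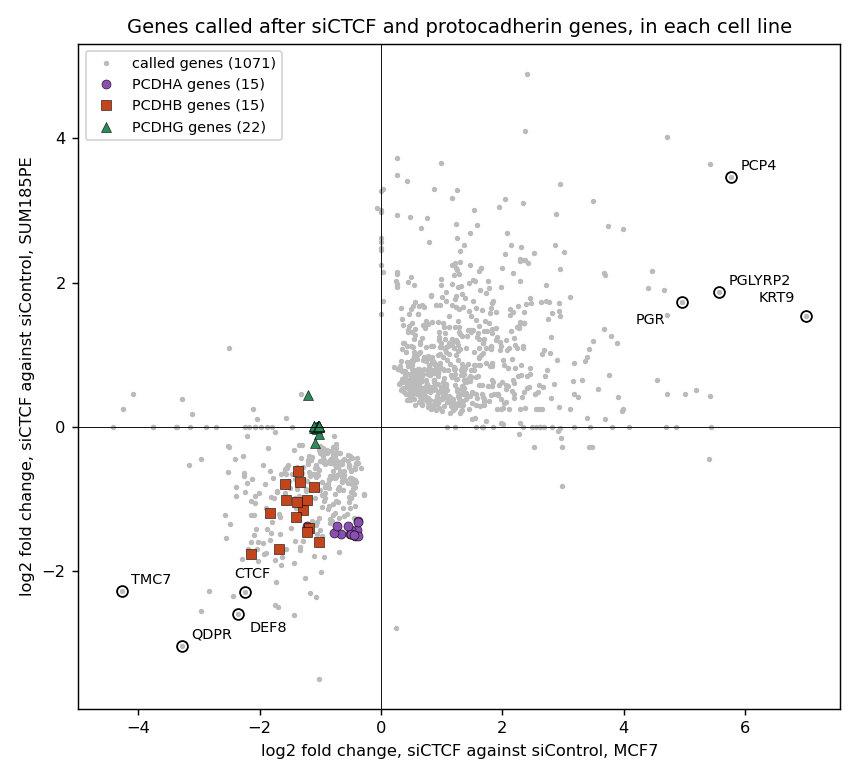
Log2 fold changes after siCTCF in MCF7 and SUM185PE of the 1071 called genes and of the 52 clustered protocadherin genes.

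Clustered protocadherins, cell adhesion genes whose promoter choice in neurons depends on CTCF, were lower after siCTCF in 52 of 52 members (median -1.0, adjusted p = 2.02e-26; 0.116 with the estimated correlation, 0.0108 in the rotation test fry). The call covered 28 of them, and 51 when adjusted over the list alone. The PCDHB genes, which are single exons and share no common exon, had 14 of 15 called with a median of -1.62 (range -2.27 to -1.29), led by PCDHB8 (-2.27, 12.2 ± 6.44 to 2.85 ± 1.06 CPM, n = 2) and PCDHB13 (-1.97), and all 15 were lower in both lines (median -1.37 in MCF7, -1.14 in SUM185PE). The PCDHA genes had 14 of 15 called (-1.04), stronger in SUM185PE (-1.47) than in MCF7 (-0.49). The 22 PCDHG genes had none called (-0.65, 21 when adjusted over the list alone), with -1.04 in MCF7 and 0.01 in SUM185PE. Members of PCDHA and of PCDHG share 3' exons, so single members of those 2 clusters cannot be told apart. The list kept its call in the fits of 6 (9.09e-32) and 4 libraries (8.05e-32), in which no single member was called. The members called were 19 without MCF7, 12 without T-47D, 20 without SUM185PE, 32 without SUM159PT, 23 without MDA-MB-231 and 14 without HCC2157.

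Cholesterol and lipid synthesis genes rose after siCTCF (median 0.48, 10 of 27 called, 13 over the list alone, adjusted p = 4.65e-07; 0.413 with the estimated correlation), among them the desaturase FADS2 (1.72), MVK (1.10), DHCR7 (0.95), MVD (0.89) and LDLR (0.46). Oestrogen response genes (0.78, 6 of 22 called, 13 alone, 0.000439; 0.413) included PGR, PDZK1 (3.08), GREB1 (1.13) and IGFBP4 (1.02), and luminal markers (0.25, 6 of 30 called, 9 alone, 0.0023; 0.116) the oestrogen receptor gene ESR1 (1.44), the prolactin receptor PRLR (1.18) and KRT19 (0.78). Interferon-stimulated genes passed upward (0.83, 7 of 27 called, 8 alone, 0.00443; 0.647) with IFIT3 (2.25), DDX60 (1.75), OAS1 (1.32) and IRF7 (1.14). S phase genes passed downward (-0.19, 0.00443; 0.497), with MCM10 (-0.80) called and 4 alone. The rotation test fry called luminal markers (0.000629), cholesterol (0.0159) and oestrogen genes (0.0238) but not S phase (0.145) or interferon genes (0.183). Without MCF7 the oestrogen (median 0.38) and interferon lists (-0.11) lost their calls, and without SUM185PE the S phase list (-0.23). That interferon median is from the fit, where the siJARID1B library also sets the level of the line. Against the SUM185PE control alone the interferon median was 0.12, with 13 of 23 members higher.

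Other lists did not pass after siCTCF, though single members were called. Basal markers (0.52, adjusted p = 0.0733) held 7 called genes, among them CD44 (3.32), KRT17 (2.21), KRT16 (2.07) and LAMB3 (0.87). TGF-beta targets (-0.36, 0.230) held SERPINE1 (-3.18), TGFB1 (-1.26), LTBP2 (-1.24) and SMAD7 (1.07), and NF-kB genes (-0.00, 0.758) TNFAIP3 (2.43), BIRC3 (2.21), RELB (0.89) and TNFAIP2 (-1.80). Among p53 targets (0.02, 0.785) GDF15 (1.32), BBC3 (1.02), PHLDA3 (0.67) and BAX (0.57) rose. The imprinted genes MEST (-1.74) and SGCE (-1.19) fell (list 0.17, 0.996). The stress list (-0.12, 0.230) held MTHFD2 (-0.97) and XBP1 (0.64), the stromal list (0.09, 0.315) VWF (1.63) and ENG (0.78), the leukocyte list (0.68, 0.315) CD68 (1.31), the CTCF and cohesin list (-0.09, 0.409) STAG1 (0.78) and the hypoxia list (0.03, 0.996) PFKFB3 (-0.92). Metallothioneins (-1.03, 0.0733), G2/M (-0.15, 0.0733), HOX (0.48, 0.0931), ribosomal protein (0.07, 0.315) and H3K4 methylation genes (0.07, 0.785) had no such gene named here.

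Set directly against siJARID1B in the same 2 lines, siCTCF left higher PGLYRP2 (5.95), PCP4 (5.59), the psoriasin gene S100A7 (5.43), SUSD2 (2.22), the luminal oncogene ZNF703 (1.55) and KRT9 (660 counts against 1). Lower were QDPR (-3.57), ZBTB39 (-2.78), PPA2 (-2.68), DEF8 (-2.42) and CTCF itself (-2.27, SE 0.15, adjusted p = 0.0182; 20.7 ± 4.92 against 96.4 ± 25.4 CPM, n = 2), while KDM5B (2.14) missed the threshold (adjusted p = 0.0719). In all 12 of 15640 genes were called (7 up, 5 down) and 2593 had an unadjusted p under 0.05. DESeq2 called 507, limma-voom 20 and a fit of all 14 libraries 1294. Either line can only be left out of that wider fit, where the count was 232 without MCF7 (KRT9, PGLYRP2, PCP4 and S100A7 not called) and 2180 without SUM185PE.

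Protocadherins were also lower after siCTCF than after siJARID1B (-1.08, adjusted p = 5.75e-42; 0.401 with the estimated correlation, 32 members alone), and cholesterol (0.58, 1.66e-09; 0.473), oestrogen response (0.88, 9.69e-08; 0.473), luminal (0.27, 5.16e-05; 0.401) and interferon genes (0.57, 0.00462; 0.707) higher. S phase (-0.30, 3.02e-05; 0.473), G2/M (-0.22, 0.00139; 0.658), TGF-beta (-0.39, 0.00332; 0.473) and stress genes (-0.33, 0.00407; 0.473) were lower. For TGF-beta targets this holds in MCF7 only (median -0.67 after siCTCF, 0.17 after siJARID1B). In SUM185PE they were higher after siCTCF (0.39 against 0.003). Stress genes were also lower after siCTCF in MCF7 only (-0.27 against 0.08), with -0.10 against -0.24 in SUM185PE. Interferon genes were higher in MCF7 (0.95 against -0.14) and hardly differed in SUM185PE (0.123 against 0.121). The rotation test fry called none of the 9 (0.208 to 0.452). In the fit of all 14 libraries the TGF-beta call ended (0.102). Out of that wider fit, the oestrogen (0.206), stress (0.0836) and interferon (median 0.10, 0.893) calls ended without MCF7, with TGF-beta at 0.893, and the G2/M call (0.15) ended without SUM185PE. The other 12 lists had an adjusted p of 0.0581 to 0.761.

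The fold changes of siJARID1B and siCTCF, which share a control library in each line, correlated across 12452 genes at 0.109 in MCF7 and 0.409 in SUM185PE. Libraries simulated with the shared control and without any effect gave 0.471 and 0.584 with Poisson noise, where no effects add spread. With negative binomial noise they gave 0.497 and 0.517. That noise took its spread from the siCTCF fit of 14 libraries. This spread holds differences in response between lines, so the second simulation is no reference free of effects. The observed covariances, 0.0179 and 0.0738, lay between the simulated ones: 0.00733 and 0.0193 with Poisson noise, 0.0626 and 0.0749 with negative binomial noise. Between siJARID1B of one of these lines and siCTCF of the other, where no control is shared, the correlation was -0.05 on average (0.01 and -0.10). Against siCTCF of MCF7 and SUM185PE, siJARID1B of T-47D correlated at 0.127 and 0.221 and siJARID1B of the 3 basal lines at -0.05 to 0.03. The T-47D fold changes rose with GC content (Spearman 0.268), as did those of siCTCF in MCF7 (0.230) and SUM185PE (0.433). The other siJARID1B pairs ran from -0.216 to 0.027. Whether GC content makes the T-47D correlation was not tested. The siCTCF fold changes of the 2 lines, also without a shared control, correlated at 0.211.

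With control siRNA, luminal lines expressed the calcium channel subunit CACNG4 (232.0 ± 93.7 CPM, n = 3, against 4 counts in the 3 basal libraries, adjusted p = 0.0344) and the homeobox gene LMX1B (log2 difference 8.72). Basal lines expressed the mesenchymal filament gene VIM (-12.93, adjusted p = 0.048), the peroxidase GPX1 (289.6 ± 153.1 CPM, n = 3, against 4 counts in the luminal libraries) and the semaphorin receptor NRP2 (-8.02). EPS8L1 (3.75), SULT2B1 (6.14), TMC4 (6.33), APCDD1L (-9.95) and TNFRSF10D (4647 counts against 4) were not called. KDM5B was 222.9 ± 48.0 CPM in luminal and 116.4 ± 45.6 in basal lines (n = 3 each, log2 difference 0.92, adjusted p = 0.687), and CTCF differed by 0.34 (0.879). Of 15017 genes, 5 were called and 1176 had an unadjusted p under 0.05, with 476 called by DESeq2 and 0 by limma-voom. The count was 37 without HCC2157 and 0 without any other single line. The class is partly confounded with the gene list used for counting: 2 of the 3 basal lines were counted with another list.

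Luminal markers had fitted values above 0 in 26 of 26 members (median 3.03, adjusted p = 4.15e-24; 0.0771 with the estimated correlation), of which 9 passed when adjusted over the list alone, with oestrogen response (2.19, 6.45e-06; 0.388), unfolded protein and stress (1.08, 0.000155; 0.388) and p53 target genes (0.91, 0.000364; 0.388) also higher in luminal lines. Basal and mesenchymal markers (-3.15, 21 of 27 lower, 2.89e-06; 0.180), NF-kB genes (-1.80, 11 of 11 lower, 0.000364; 0.742), ribosomal protein (-0.51, 0.00484; 0.742), G2/M (-0.37, 0.0226; 0.742) and hypoxia genes (-0.58, 0.0336; 0.742) were higher in basal lines. Protocadherins passed upward on their mean (1.26, 0.00256; 0.742) with a median of -0.30. The ribosomal call ended without T-47D (0.0724), SUM185PE (0.241), SUM159PT (0.161) or HCC2157 (0.0791), and the protocadherin call without SUM159PT (0.132) or MDA-MB-231 (0.221). G2/M ended without SUM185PE (0.234), MDA-MB-231 (0.611) or HCC2157 (0.216), and hypoxia without SUM185PE (0.241) or MDA-MB-231 (0.672). In the 4 lines of the first gene list p53 (0.155) and hypoxia (0.454) ended, and G2/M ended and turned (median 0.45, 0.146). The rotation test fry called luminal markers (0.0399) and none of the other 9 (0.136 to 0.638). The other 11 lists had an adjusted p of 0.0672 to 0.856.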

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

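The test for a line that stands apart and the test between classes were fixed before the results. Of the tests below, those of shared exons, of GC content and of RNA from other lines were chosen after the result they address was seen.

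SUM159PT stood apart from the other 5 lines after siJARID1B. The SD of its log2 fold changes was 0.66 (others 0.15 to 0.30), with 407 genes at least 2-fold higher (3 to 65) and 718 at least 2-fold lower (6 to 39). List medians far from the others were those of stress response genes (1.36; others -0.24 to 0.14), hypoxia and glycolysis (1.16; -0.28 to 0.01), NF-kB (-0.52; -0.02 to 0), protocadherins (-1.05; -0.07 to 0.34) and endothelial and stromal markers (-0.95; -0.28 to 0.01). Its libraries could be too shallow, but the other pairs thinned to its depth reached an SD of at most 0.318, so depth alone gives no such width. Neither does GC content (SD 0.663 without the GC trend) or RNA of another line of the series (a median rise of 0.0757% of that line's level at most, and 0.259% of the summed level, both for T-47D). A culture or transfection that went differently, an off-target effect and a stronger response of this line remain open hypotheses that 1 pair cannot part.

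Other single lines were flagged as far from the rest after siJARID1B: T-47D in oestrogen response genes (-0.14; others -0.02 to 0.04) and CTCF and cohesin genes (-0.18; -0.01 to 0.06), SUM185PE in S phase genes (0.33; -0.04 to 0.05), and MCF7 in SNAR-A10 and SNAR-A11 (0.10; 1.47 to 2.22). In all 13 of 50 groups were flagged, where chance flags about 2.5 if groups are independent. They are not: SNAR-A10 and SNAR-A11 have the same values, and 3 of the 13 measure the width in SUM159PT, so the 2 numbers are no test.

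The siJARID1B effect was flagged as different between luminal and basal lines in 9 lists: protocadherins (0.38), endothelial and stromal (0.43), basal markers (0.21), TGF-beta (0.14), S phase (0.14), G2/M (-0.26), p53 (-0.26), hypoxia (-0.35) and stress response (-0.47). None was called with the estimated correlation between genes or by the rotation test fry, and 5 were called without SUM159PT.

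In the fit, protocadherins were lower after siCTCF in 52 of 52 members. By line 52 were lower in MCF7 and 37 in SUM185PE, where the 22 PCDHG genes had a median of 0.01. Shared exons, GC content and scaling were looked at as technical explanations. Reads shared through the common exons of PCDHA and PCDHG could spread 1 change over many symbols. The PCDHB genes, which have no common exon, had a median of -1.62, so the fall of these genes does not come from shared exons. For the other 2 clusters this decides nothing. Their members moved almost as 1 signal each, with a median correlation between members of 0.993 (PCDHA) and 0.998 (PCDHG). GC content could move the protocadherins, since siCTCF fold changes followed GC (Spearman 0.230 in MCF7 and 0.433 in SUM185PE), but the list stayed at -0.95 after the correction. With RLE size factors the median of the list was -1.0, and with library size only -1.08. Relative to all genes it was -1.03 at most, but that value cannot move with the scaling and tests nothing. A loss of CTCF at the promoters and enhancers of the clusters is an open hypothesis, and a transcript measure alone does not test it.

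Basal and mesenchymal markers were higher after siJARID1B in luminal lines, with a median of 0.24 in the fit but 0.03 in T-47D. RNA from a basal line of the series could do this, but other genes of those lines rose by a ratio of at most 0.0425 of the share needed, and after the GC correction the median was 0.25, so neither accounts for it. With the correlation between genes estimated, the list did not pass (adjusted p = 0.140). Its median was also above 0 after siCTCF against the same control libraries (0.26 in MCF7, 0.46 in SUM185PE), so a rise is not particular to siJARID1B.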

How the results depend on the processing

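The alternatives were fixed before the files were opened, except the GC correction, the fits by gene list, the genes with the same length in both gene lists and the PCDHB genes alone. Of the values that carry the report, 154 stayed the same, 71 counts moved by over 1.5 times and 3 became weaker, and of the other values 1007 stayed, 152 weakened, 64 strengthened and 17 reversed. Where no cause is named below, the cause was not tested. Smaller sets of libraries and left-out lines have fewer samples by construction. Depth limits genes near 3 counts (0.0711 to 0.423 CPM).

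Over the 6 lines siJARID1B called 1 gene, 14 without a filter, 40 with DESeq2, 4 with limma-voom, 49 without SUM159PT (1 without any other line), 34 in the lines of the second gene list, and 0 with no replicate block. Without that block KDM5B was at -2.29 and not called, and 3 lists were called in place of 7. With the correlation estimated 0 lists were called in each of the 7 comparisons, against 7, 6, 8, 9, 6, 9 and 10. Without a filter the G2/M and stromal calls over the 6 lines ended (adjusted p = 0.0539 each), as did S phase and TGF-beta in the difference of the classes (0.0525 each; S phase also with library size only, 0.0605). In the lines of the second gene list the stress call ended (0.605), basal markers ended and turned (-0.03, 0.744) and G2/M turned (-0.10, 0.00821). With no replicate block the calls of basal markers, interferon genes and metallothioneins (0.176 each) and stromal markers (0.867) ended, as did S phase (0.609) and, turned downward, interferon genes (0.320) after siCTCF.

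In luminal lines the 1 call became 0 with RLE size factors, library size only, a mean CPM of at least 5 or the GC correction, 2 without a filter, 7 with DESeq2, and 54 in the 6 luminal libraries. Leaving out lines gave 0 (MCF7, T-47D, SUM185PE) to 41 (SUM159PT). In basal lines the 13 calls became 7 with library size only, 42 without a filter, 1 at a mean CPM of at least 5, 30 with DESeq2, 22 with limma-voom and 0 in the 6 basal libraries. Leaving out lines gave 0 (MCF7, T-47D, SUM185PE) to 25 (HCC2157), with 23 without MDA-MB-231. The difference of the classes went from 0 calls to 2 without a filter, and leaving out lines gave 0 to 2 (1 without SUM159PT, 2 without MDA-MB-231, 1 without HCC2157) and 5 lists without SUM159PT.

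Small values near 0 reversed. CTCF after siJARID1B ran from -0.0475 (without T-47D) to 0.00647 (without SUM185PE) in luminal lines over the left-out lines, and from -0.223 (without HCC2157) to 0.00135 (without SUM159PT) in basal lines. Its class difference ran from -0.0277 (without SUM159PT) to 0.195 (without HCC2157). The class difference of KDM5B was -0.0363 with limma-voom and ran from -0.16 (without SUM159PT) to 0.61 (without HCC2157), with -0.13 without SUM185PE. KDM5B after siCTCF ran from -0.34 (without MCF7) to 0.10 (without SUM185PE). It was 0.0498 and 0.0742 in the fits of 6 and 4 libraries, 0.00476 after the GC correction and 0.27 with no replicate block. In the siCTCF fit the siJARID1B libraries also set the level of a line. Against the control of the line alone KDM5B stood at 109% in MCF7 and 102% in SUM185PE, so the -0.34 is no fall against that control.

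For siCTCF the 1071 calls became 1911 with DESeq2, 10 in 6 libraries and 2 in 4 libraries (11 lists each), and 0 with no replicate block. Leaving out lines gave 224 (MCF7) to 2179 (SUM159PT), with 516 without T-47D, 1956 without SUM185PE, 685 without MDA-MB-231 and 645 without HCC2157. CTCF was at -1.89 with no replicate block and -2.28 in 4 libraries (adjusted p = 0.0799), not called in either. With no replicate block the siCTCF libraries of 2 lines are set against the siControl libraries of all 6, and KLK8 (-1.85), SLC2A14 (-3.63), THRSP (-0.63), PGR (-1.82), CD274 (-0.80) and SERPINA1 (-2.22) reversed. The counts that did not move by over 1.5 times were 1054 (RLE), 907 (library size only, 51.6% of them up against 69.3%), 1218 (no filter), 953 (mean CPM of at least 5), 1439 (limma-voom) and 719 (GC-corrected).

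For siCTCF against siJARID1B the 12 calls became 20 with library size only, 61 without a filter, 5 at a mean CPM of at least 5, 507 with DESeq2, 20 with limma-voom and 1294 in all 14 libraries. Leaving a line out of that wider fit gave 232 (MCF7, 5 lists) to 2180 (SUM185PE). With control siRNA the 5 calls became 476 with DESeq2, 0 with limma-voom and 0 in the lines of the first gene list, and leaving out lines gave 0 (every line but HCC2157) to 37 (HCC2157). The correlation of the knockdowns kept its sign: 0.259 on average in a line became 0.287 and 0.237 at prior counts of 1 and 20 and 0.240 at a mean CPM of at least 10, and -0.0452 across lines became -0.0250, -0.0661 and -0.0577.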

Other observations

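The class similarity was tested after the results were seen, and the splits were fixed before them. In MCF7 alone siCTCF left the stratified-epithelium keratin KRT13 at 125-fold its control level (interval 100.3 to 158.6) and PCP4 at 61.8-fold, with the endopeptidase MME at 3 counts (1.05%, 0.215 to 3.08), TMC7 at 3.39% and the vitamin D hydroxylase CYP24A1 at 4.11%. In SUM185PE alone the hair keratin KRT36 went from 0 counts to 165 (at least 23.6-fold), the meiosis gene SYCE3 rose from 2 counts (33.3-fold, from 9.06) and the metalloproteinase inhibitor TIMP3 stood at 18.4-fold. PLCXD3 (10.8%), QDPR (11.4%) and HSD17B2, which inactivates oestradiol (13.9%), were lower there. PLCXD3 was low in SUM185PE after both siRNAs (7.59% after siJARID1B), and both are set against the same control library.

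The relatives of KDM5B stayed near their control levels except for KDM5C at 125% in SUM159PT after siJARID1B and 127% in SUM185PE after siCTCF, and KDM5A at 80.4% in SUM185PE after siCTCF. Small non-coding RNA genes, which polyA selection should remove, summed to 1442 CPM in SUM159PT (2136 after siJARID1B), 458 in SUM185PE (798 after siJARID1B, 1154 after siCTCF), 248 in MCF7 (354, 532) and 1139 in HCC2157 (764).

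Chance groupings were tested by counting calls in other splits of the libraries. For siJARID1B over 6 lines 19 of 80 splits had as many called genes as the real one (1, highest other 152), 34 of 80 as many lists (7, highest other 11), and of 32 label swaps within pairs 2 had as many genes (1, highest other 3) and 18 as many lists (7, highest other 11), so chance cannot be excluded for these counts by the splits. The counts of splits and of swaps both include the real labels. Among the 80 drawn splits, 78 besides the real one called at least 1 list (median of the others 6). The split with 152 called genes parted only 2 of the 6 pairs.

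The 10 splits of 6 libraries of a class, or of the 6 lines, are too few for a share under 0.05. As many genes were called in 1 of 10 for luminal lines (1, highest other 0), 3 of 10 for basal lines (13, highest other 3603, in splits where only the SUM159PT pair is parted), 10 of 10 for the difference of the classes (0, highest other 1) and 1 of 10 with control siRNA (5, highest other 0). As many lists were called in 3 (6, highest other 9), 1 (8, highest other 7), 1 (9, highest other 8) and 2 (10, highest other 12) of 10.

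A shared response of lines of one class was tested by the mean correlation of siJARID1B fold changes, 0.112 within and 0.101 between classes. An excess as large came in 3 of 10 splits (highest other 0.0271, exact p = 0.3, smallest possible 0.1), so this test cannot tell.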
